A study of Mus musculus with 9 samples.

How the data were processed

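Striatal RNA of 9 male C57BL/6J mice aged 56 days was measured on single-colour Affymetrix mouse expression arrays, 1 array per mouse. The labels put 3 arrays in each of 3 groups: saline-injected controls, mice injected with methamphetamine (METH), and mice injected with MPTP. They call the arrays of a group biological replicates. Doses, injection schedules and the time from injection to dissection are not given in the sources used here.

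The deposited table holds 1 value for each of 22690 probe sets on each array, and the unit was taken as a linear intensity, from the values and the labels, since it ran from 0.342 to 84013. A probe set is a group of short oligonucleotides whose brightness is summarised into 1 signal. Each array had a trimmed mean of 2501 (2% left out at each end), so the arrays had been scaled to a common target before deposit. The array medians were 1124, 1127 and 1110.5 in control 1, 2 and 3, 1156, 1233 and 1127 in METH 1, 2 and 3, and 1127.5, 1151 and 1178 in MPTP 1, 2 and 3. RMA is named in the submitters' processing notes, with no version or settings. The deposited intensity values do not have the form that RMA usually gives, which is a log scale with nearly equal distributions and little spread among dim probe sets. How each probe set was summarised is therefore unsettled. The scale was settled as linear from the values, the values were not centred by gene, and a direction between dyes does not apply to single-colour arrays. The submitters' text names a larger array design than the one whose probe annotation matched the deposited values. Spearman correlations between arrays were 0.97 to 0.985. METH 2 had the highest median and the narrowest distribution, with 6.25 log2 units between its 10th and 90th percentiles against 6.4 to 6.69 on the other arrays. Signal ratios of 3' to 5' control probe sets, a gauge of RNA quality, overlapped between groups. For pyruvate carboxylase they were 2.46 to 3.38 in control, 1.42 to 2.89 in METH and 2.16 to 2.95 in MPTP. For the transferrin receptor they were 2.2 to 2.81, 2.25 to 2.94 and 2.76 to 3.73. The Gapdh ratio was lowest in METH 2, 0.73. Whether RNA quality bears on the group differences was not tested.

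Of the 22690 probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none listed; a further 64 were array controls. Symbols were looked up by gene ID in an NCBI RefSeq gene table of assembly GRCm38.p6, which held 20351 of the 20380, and 0 symbols changed. No coordinates were used. Values were put on the log2 scale as deposited, with no further normalization and no pseudocount. Probe sets with a mean log2 value under the 40th percentile of all probe sets (9.53, a signal of 741) were left out, and each gene was represented by its probe set of highest mean. This left 7964 of 12393 genes. Among all probe sets the median SD within groups fell from 0.82 log2 units in the dimmest 10% to 0.11 in the brightest 10%, and no detection calls were used here.

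Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group, then eBayes), with all 9 arrays in 1 fit, 6 residual degrees of freedom and 3.9 prior degrees of freedom. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 counted as past the test. The ± after a log2 fold change is its SE in that fit, and the ± after a signal is the SD of 3 arrays. For 3 arrays against 3, an exact permutation test of a single value cannot go below p = 0.1, so none was used between pairs of groups. The number of arrays limits the precision of every value.

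Gene lists for cell types, pathways and complexes were written down before the data were examined, together with the design, the alternatives and the rule for naming genes. Of 33 lists, 31 had at least 5 genes tested. The blood cell list had 4 and the list of indirect-pathway spiny neuron markers had 3, so these were reported gene by gene against control. Lists were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 31 lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were run as alternatives. Estimated correlations were 0.07 for microglia markers, -0.01 for interferon-responsive genes, 0.19 for complex I, 0.06 for complexes II to V and 0.21 for immediate early genes. Where they exceed 0.01, set test p-values at the preset correlation may be too small. A list score is the mean, over the genes of a list, of the log2 deviation from the mean of all 9 arrays. Each list's median was also ranked among 10000 random lists of genes matched on mean expression.

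The rule named the 10 genes with the smallest p where fewer than 5 genes passed in a comparison, up to 4 genes with the smallest p in each list, and a fixed set of dopamine, astrocyte and spiny neuron genes. Of this fixed set, Slc18a2 and Drd1 had no probe set with 1 symbol and were not analysed here, and Slc6a3 lay below the filter.

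The METH and MPTP comparisons share their controls. The correlation, covariance and overlap that shared controls give without any effect were taken from 100 simulations of 9 unchanged arrays with each gene's own spread. Genes were drawn independently, so correlation between genes is left out. The fits were tested on simulated data for METH against control, with 50 of 7964 genes changed at each fold in 20 draws. At the 0.05 threshold 56.4% of genes changed 1.5-fold were recovered, 89.5% of those changed 2-fold and 97.8% of those changed 3-fold, and 5.1% of calls were false. A list shifted by 0.15 log2 units was called in 19 of 20 draws. These draws had noise independent between genes, and the genes of all folds were changed together. Many changed genes ease the Benjamini-Hochberg cutoff, so the recovery rates may be too high for data where few genes pass.

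The alternatives were no filter or a filter at the 60th percentile, quantile normalization, arrays centred on their medians, other choices of probe set, only the groups compared in the fit, the replicate number as a block, array weights, a trended and robust prior, other thresholds, the other list tests, and leaving out each array in turn. Chosen after seeing the data were log2 of the value plus 100, cyclic loess, the counts at an unadjusted p, the ranks among matched random lists, and exact permutation tests of list scores over the 84 splits of 9 arrays into 6 and 3. Codon usage and microRNA target sites need transcript sequences and were not analysed here.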

Results

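Gene expression was measured in the striatum of 9 male mice, 3 injected with saline, 3 with methamphetamine (METH) and 3 with MPTP. METH is a psychostimulant that drives dopamine out of nerve terminals and damages them at high doses. MPTP is converted in the brain to a toxin that dopamine neurons take up. Both are used to model the loss of striatal dopamine in Parkinson's disease. Every array gave a value for 22690 probe sets, and 7964 genes entered the tests. The comparisons ask which striatal transcripts differ from saline after each toxin, and whether the toxins differ from each other.

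Gfap, the intermediate filament gene of astrocytes, rose 2.19-fold in the METH striatum. Its signal was 5619.9 ± 732.5 in control mice and 12286 ± 1444 in METH mice (SD, n = 3 each), a log2 fold change of 1.13 ± 0.13 with adjusted p = 0.04. All 3 METH arrays lay above all 3 control arrays, and both Gfap probe sets gave the same sign. Microglial and interferon-responsive transcripts were higher as groups, and transcripts for the mitochondrial respiratory chain, the proteasome and presynaptic proteins were lower as groups. These group differences were small, with medians of 0.11 to 0.19 log2 units in size, and each of their calls was lost when the correlation between genes was estimated.

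Gfap was 1 of 7964 genes past the test in METH against control, in limma. At an unadjusted p under 0.05 there were 657 genes, 414 higher and 243 lower, where chance gives 398. The groups did not overlap for 13.7% of genes, where chance gives 10%. The other genes with the smallest p did not pass. Sox10, a transcription factor of the oligodendrocyte lineage, had a log2 fold change of 0.64 ± 0.10 and an adjusted p of 0.175. Lor, which encodes a protein of the cornified skin envelope, had 1.33 ± 0.20, and Dcaf12 had 1.02 ± 0.18. Abca1, a cholesterol exporter, had 0.55 ± 0.10, and Lpcat3, a phospholipid-remodelling enzyme, had 0.61 ± 0.10. Zfp395 and Jph1 had 0.59 ± 0.12 and 0.56 ± 0.11. Lower values were found for Cabp1, a neuronal calcium-binding protein, at -0.58 ± 0.11, and for Nup107, a nuclear pore component, at -0.76 ± 0.15. Adjusted p-values of these genes after Sox10 and Lor were 0.303 to 0.343.

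**Figure D1:**
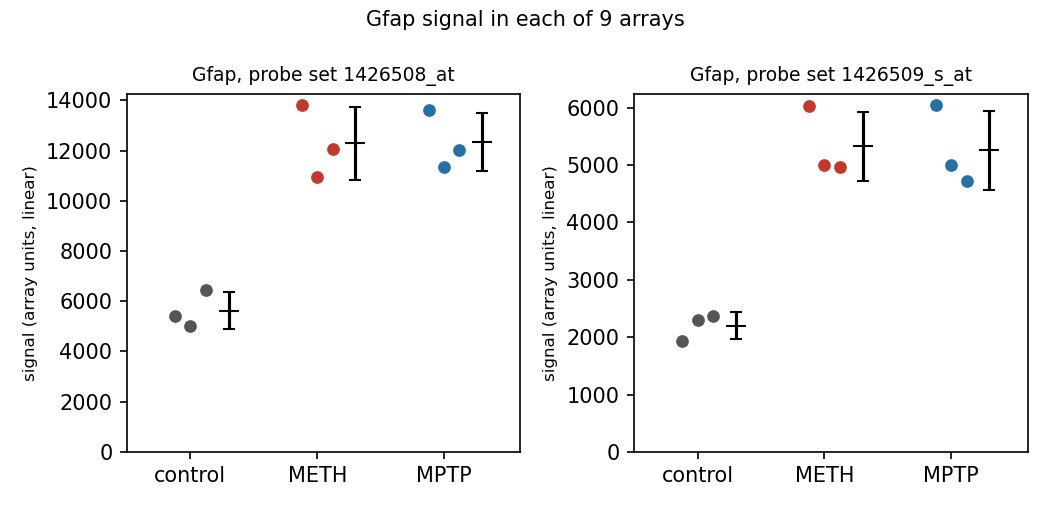
Signal of the 2 Gfap probe sets (linear array units) in each control, METH and MPTP array, with the mean and SD of 3 arrays beside the points. The values of the brighter probe set lie at 5020.2 to 6436 in control, 10957 to 13823 in METH and 11350.3 to 13596 in MPTP.

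Microglia and macrophage markers were higher after METH for 28 of 29 genes, with a median log2 fold change of 0.19 (set test adjusted p = 3.47e-08, and adjusted p = 0.099 with an estimated correlation). Among them were Fcrls (0.44 ± 0.10), the protease gene Ctss (0.43 ± 0.11), the signalling adaptor Tyrobp (0.33 ± 0.10) and Ly86 (0.51 ± 0.17). Of the 29, 2 passed when adjusted over the list alone, Ctss and Fcrls, and over all genes tested 0 did. Without METH 3 the median was 0.29. The haemoglobin gene Hbb-b2 moved the same way, with 0.69 ± 0.23 (adjusted p = 0.543). Among the other blood genes tested, Ighm and Ngp had 0.17 ± 0.17 and 0.21 ± 0.23, and Ltf had -0.17 ± 0.20. Interferon-responsive genes were higher for 14 of 15, with a median of 0.17 (adjusted p = 1.97e-04, and adjusted p = 0.099 with an estimated correlation). The guanosine triphosphatase gene Irgm1 had 0.62 ± 0.14, the transcription factor gene Irf1 0.68 ± 0.23 and the class I histocompatibility gene H2-D1 0.48 ± 0.17. Irgm1 was the 1 gene of this list that passed when adjusted over the list alone, and over all genes tested 0 did. The median of the interferon list was 0.10 with quantile normalization, 0.09 with cyclic loess, 0.11 with arrays centred on their medians, 0.48 with a filter at the 60th percentile, and 0.26 with array weights or without control 3.

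Respiratory chain transcripts were lower after METH. Complexes II to V, which pass electrons to oxygen and make ATP, had 37 of 39 genes lower, with a median of -0.13 (adjusted p = 1.11e-06, and adjusted p = 0.122 with an estimated correlation). Cycs, which encodes cytochrome c, had -0.29 ± 0.08, the ATP synthase subunit gene Atp5j had -0.20 ± 0.08 and the complex III subunit gene Uqcrh had -0.25 ± 0.10. Complex I, the entry point for electrons from NADH, had 31 of 33 genes lower, with a median of -0.12 (adjusted p = 5.06e-06, and adjusted p = 0.283 with an estimated correlation). Its smallest p-values were those of Ndufb8 (-0.31 ± 0.10), Ndufb2 (-0.23 ± 0.08) and Ndufa1 (-0.23 ± 0.08). No gene of either list passed when adjusted over the list alone (0 of 39 and 0 of 33), nor over all genes tested. Quantile normalization left medians of -0.07 and -0.08 for these lists, with adjusted p = 0.0162 for both, and cyclic loess left -0.07 for both. Arrays centred on their medians moved them the other way, to -0.19 for both (adjusted p = 2.05e-05 for complex I and 2.60e-06 for complexes II to V). The array that stood apart in its distribution, METH 2, had the lowest complex I score of the 9 arrays, -0.113.

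Proteasome subunit genes were lower after METH for 29 of 32, with a median of -0.11 (adjusted p = 2.85e-04, and adjusted p = 0.283 with an estimated correlation). Psmc4 had -0.22 ± 0.09 and Psma5 -0.29 ± 0.12, whereas Psmd13 had 0.31 ± 0.11, and the median was -0.17 with arrays centred on their medians. Synaptic vesicle and presynaptic genes were lower for 16 of 20, with a median of -0.13 (adjusted p = 0.016, and adjusted p = 0.562 with an estimated correlation). Cplx2 had -0.32 ± 0.11 and the vesicle protein gene Syp -0.24 ± 0.09, and the active zone gene Bsn had 0.38 ± 0.14. In both lists 0 genes passed when adjusted over the list alone, and 0 over all genes tested. Cortical glutamatergic markers were chosen to mark tissue outside the striatum, though the list shares some genes with the spiny neuron and presynaptic lists. They had a median of -0.19 and did not pass (set test adjusted p = 0.051). The presynaptic call ended with quantile normalization (adjusted p = 0.344), cyclic loess (0.328) and the mean of all probe sets (0.0502), and without control 1, control 3, METH 1 or METH 2 (adjusted p = 0.051 to 0.184).

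Reactive astrocyte genes other than Gfap gave smaller values after METH. Vim, another intermediate filament gene, had 0.43 ± 0.13, the ferroxidase gene Cp had -0.88 ± 0.33, and the list of 15 had a median of 0.06 (adjusted p = 0.11). Gfap passed when adjusted over the list alone and over all genes tested. Sox10 in the myelin list and Hk2, a hexokinase gene (0.50 ± 0.10), in the glycolysis list passed over the list alone and not over all genes. The water channel gene Aqp4 had 0.28 ± 0.08 among 21 astrocyte markers with a median of 0.01 (adjusted p = 0.533). Th, the rate-limiting enzyme gene of dopamine synthesis, had 0.04 ± 0.16 (adjusted p = 0.956), and Ddc, which encodes the next enzyme, had 0.41 ± 0.16. Of 17 dopamine neuron and terminal genes 5 were tested, and this list had a set test adjusted p of 0.312. Loss of dopamine terminals was not measured here. Tac1, a neuropeptide gene of direct-pathway spiny neurons, had -0.26 ± 0.10. Drd2, Penk, Pdyn and Ppp1r1b had -0.11 ± 0.11, -0.05 ± 0.10, -0.14 ± 0.15 and 0.03 ± 0.11. Plxdc1, the indirect-pathway marker tested beside Drd2 and Penk, had 0.12 ± 0.09. Pan-striatal spiny neuron markers had a median of 0.02 over 23 genes (adjusted p = 0.873). With fry the complex I, proteasome and presynaptic calls ended (adjusted p = 0.0976, 0.0761 and 0.345). The 25 lists that did not pass had adjusted p-values of 0.051 to 0.98. Among them, oligodendrocyte precursor markers had a median of -0.01, a mean of 0.01 and a test pointing up, and glucocorticoid-responsive genes a median of 0.02, a mean of 0.01 and a test pointing down.

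The Gfap call in METH ended with arrays centred on their medians (adjusted p = 0.106), with no filter (0.137) and with only METH and control in the fit (0.148), at log2 fold changes of 1.07 to 1.13. It also ended without control 1, control 2, METH 1, METH 3, MPTP 1 or MPTP 3, at 1.04 to 1.14 and adjusted p-values of 0.078 to 0.273.

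In the MPTP striatum Gfap again rose, 2.2-fold, to a signal of 12324 ± 1152 against 5619.9 ± 732.5 in control mice (SD, n = 3 each). The log2 fold change was 1.14 ± 0.13 with adjusted p = 0.038, and all 3 MPTP arrays lay above all 3 control arrays. Microglial, interferon-responsive and myelin transcripts were higher as groups. Immediate early genes and complex I subunits were lower as groups. As with METH, the medians were small and each group call was lost when the correlation between genes was estimated.

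Gfap was 1 of 7964 genes past the test in MPTP against control, in limma. At an unadjusted p under 0.05 there were 437 genes, 282 higher and 155 lower, where chance gives 398. The groups did not overlap for 11.3% of genes, where chance gives 10%. The next genes by p had adjusted p-values of 0.454 to 0.672. Among them, Hk2, a hexokinase of glycolysis, had 0.61 ± 0.10, Plxnb3, a semaphorin receptor, had 0.52 ± 0.10, and Lce1b had 0.74 ± 0.13. Abca1 and Ell had 0.48 ± 0.10 and 0.42 ± 0.08. Lower values were found for Dusp1, a phosphatase gene induced by neuronal activity, at -0.56 ± 0.11, and for Tasp1, Nup107 and Cabp1 at -0.52 ± 0.09, -0.79 ± 0.15 and -0.52 ± 0.11. Abca1, Nup107 and Cabp1 were also among the 10 genes with the smallest p after METH, with the same sign.

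Microglia and macrophage markers were higher after MPTP for 27 of 29 genes, with a median of 0.20 (adjusted p = 7.27e-07, and adjusted p = 0.231 with an estimated correlation). Lyz2, the macrophage lysozyme gene, had 0.60 ± 0.16, Ly86 had 0.53 ± 0.17, and Fcrls and Ctss had 0.36 ± 0.10 and 0.35 ± 0.11. Hbb-b2 again moved the same way, with 0.57 ± 0.23 (adjusted p = 0.873), while the blood genes Ighm, Ltf and Ngp had 0.20 ± 0.17, 0.10 ± 0.20 and 0.17 ± 0.23. Interferon-responsive genes were higher for 12 of 15, with a median of 0.18 (adjusted p = 0.01, and adjusted p = 0.231 with an estimated correlation), and the call ended without control 1 (median 0.11, adjusted p = 0.056). Irgm1 and Irf1 had 0.53 ± 0.14 and 0.57 ± 0.23, and the antiviral gene Rsad2 had 0.32 ± 0.14. Oligodendrocyte and myelin genes were higher for 22 of 24, with a median of 0.16 (adjusted p = 2.31e-06, and adjusted p = 0.397 with an estimated correlation). Sox10 had 0.34 ± 0.10, the tight junction gene of myelin Cldn11 0.28 ± 0.08, Gal3st1, which sulphates myelin lipids, 0.28 ± 0.09, and Olig2 0.32 ± 0.10. These 3 lists had 0 genes past the test when adjusted over the list alone, and 0 over all genes tested.

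Immediate early genes, which neurons switch on within minutes of activity, were lower after MPTP for 18 of 24, with a median of -0.22 (adjusted p = 2.63e-05, and adjusted p = 0.397 with an estimated correlation). Fos had -0.51 ± 0.13, Dusp14 -0.45 ± 0.16 and Dusp6 -0.42 ± 0.15. When adjusted over the list alone 2 passed, Dusp1 and Fos, and over all genes tested 0 did. MPTP 2 had the lowest score of the 9 arrays, -0.283, and control 3 the highest, 0.237, while the scores of the other 2 MPTP arrays, -0.034 and -0.03, lay above that of control 1, -0.045. Without MPTP 2 the median was -0.13 (adjusted p = 0.0299). The list of 15 circadian clock genes had a median of -0.12 (adjusted p = 0.043, and adjusted p = 0.421 with an estimated correlation), with the smallest p for Per2 (-0.31 ± 0.14). The clock call ended with quantile normalization (adjusted p = 0.0654), arrays centred on their medians (0.0506), array weights (0.11) and cyclic loess (0.067), and without control 1, control 2, MPTP 2 or MPTP 3 (adjusted p = 0.054 to 0.586, with a median of -0.03 without MPTP 2).

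**Figure D2:**
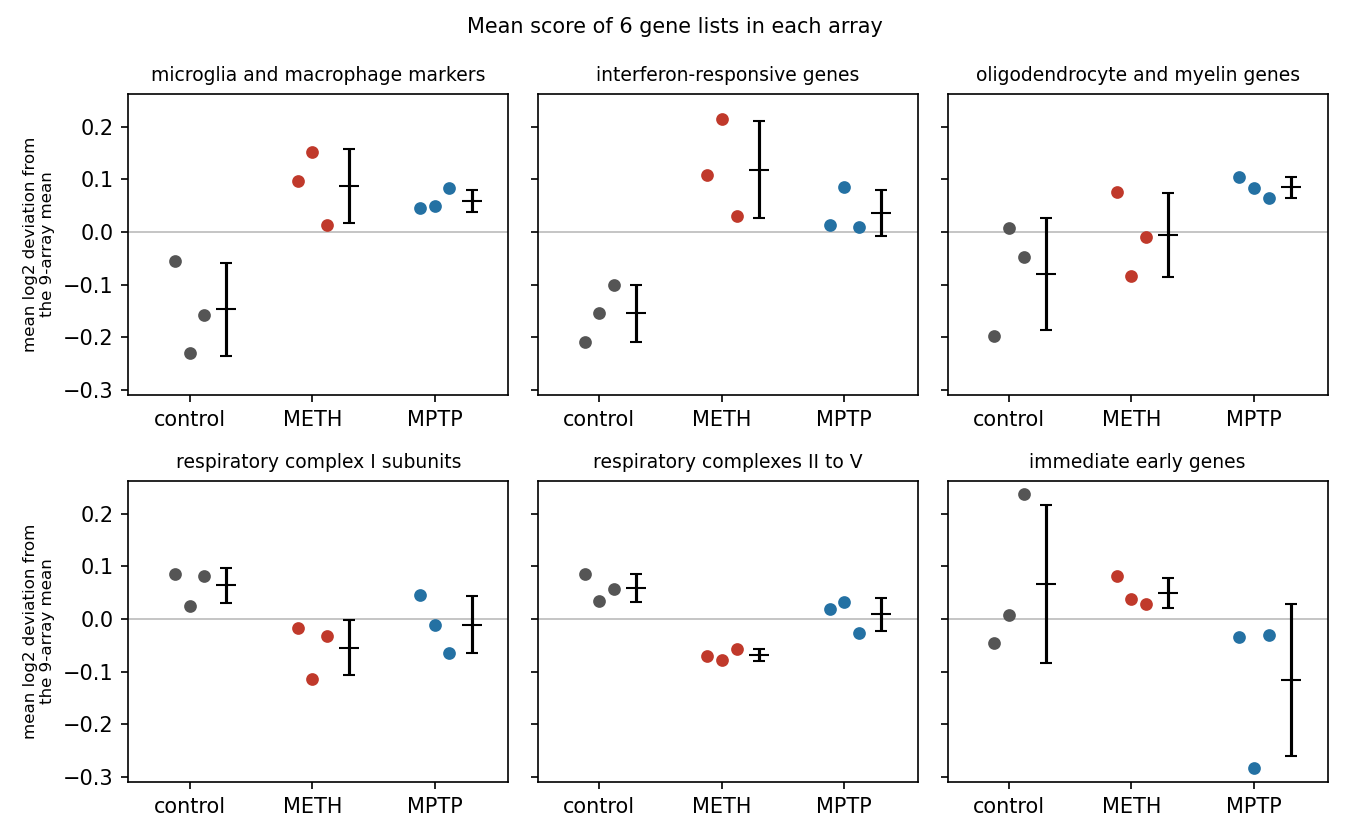
Scores of 6 gene lists (mean log2 deviation from the mean of 9 arrays, over the genes of each list) in each control, METH and MPTP array, with the mean and SD of 3 arrays beside the points. Microglia scores lie at -0.229 to -0.054 in control, 0.013 to 0.152 in METH and 0.046 to 0.084 in MPTP.

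Respiratory chain genes were also lower after MPTP. Complex I had 27 of 33 genes lower, with a median of -0.08 (adjusted p = 5.51e-04, and adjusted p = 0.421 with an estimated correlation), and the median was -0.05 without MPTP 3 (adjusted p = 0.0438) and with quantile normalization (0.0457). Ndufb7 had -0.25 ± 0.11 and Ndufa4 -0.20 ± 0.09. Complexes II to V had 29 of 39 genes lower, with a median of -0.06 (adjusted p = 0.039, and adjusted p = 0.421 with an estimated correlation), and Cycs had -0.16 ± 0.08. This call ended with quantile normalization (adjusted p = 0.63), cyclic loess (0.621), a filter at the 60th percentile (0.0673) and _x_at and _s_at probe sets left out (0.0859), and without control 1, control 3 or MPTP 3 (adjusted p = 0.086 to 0.244, with a median of -0.03 without MPTP 3). Arrays centred on their medians gave -0.10. Presynaptic genes had a median of -0.06 (adjusted p = 0.045, and adjusted p = 0.525 with an estimated correlation), with the smallest p for Syn1 (-0.35 ± 0.12), a call that ended with each of quantile normalization (adjusted p = 0.373), cyclic loess (0.345), centring on array medians (0.0583), a filter at the 60th percentile (0.0859) and the mean of all probe sets (0.104). It also ended without any 1 array other than control 2 and METH 3 (adjusted p = 0.052 to 0.38), and without control 2 its median was -0.12. For these 3 lists, 0 genes passed when adjusted over the list alone and 0 over all genes tested.

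Endothelial and pericyte markers had a median of -0.08 after MPTP (adjusted p = 0.045, and adjusted p = 0.491 with an estimated correlation), with the smooth muscle actin gene Acta2 at -0.37 ± 0.14 and Cd34 at -0.25 ± 0.10. This call ended with array weights (median -0.03, adjusted p = 0.3), a filter at the 60th percentile (0.285), the mean of all probe sets (median -0.04, adjusted p = 0.0684) and _x_at and _s_at probe sets left out (0.0673). It also ended without control 1, control 2, METH 2, MPTP 1 or MPTP 3 (adjusted p = 0.06 to 0.334), and the median was 0 without control 1 and -0.05 without control 2. Choroid plexus and ependymal markers, which mark ventricular tissue, were lower for 7 of 8 genes, with a median of -0.29 (adjusted p = 0.031, and adjusted p = 0.491 with an estimated correlation). That call ended with array weights (median -0.17, adjusted p = 0.166) and the mean of all probe sets (0.137), while no filter gave a median of -0.47. It also ended without control 1, MPTP 2 or MPTP 3 (adjusted p = 0.064 to 0.253), at medians of -0.14, -0.43 and -0.18. Ttr, the abundant transthyretin gene of choroid plexus, ranged from 2853 in MPTP 2 to 65370 in control 1 and had -1.76 ± 0.96. Here and in the clock list 0 genes passed when adjusted over the list alone, and 0 over all genes tested. Among genes of lists that did not pass, Th had -0.13 ± 0.16 and Ddc 0.50 ± 0.16 (dopamine list adjusted p = 0.448). Hk2 passed in the glycolysis list when adjusted over the list alone, while the list had a median of -0.02 and a mean of 0.01 (adjusted p = 0.741, test pointing down). Vim had 0.30 ± 0.13 and Aqp4 0.31 ± 0.08. Tac1, Drd2, Penk, Pdyn and Ppp1r1b had -0.21 ± 0.10, -0.18 ± 0.11, -0.05 ± 0.10, 0.02 ± 0.15 and -0.08 ± 0.11. Plxdc1 had -0.03 ± 0.09. With fry all 10 calls ended (adjusted p of at least 0.089). The 21 lists that did not pass had adjusted p-values of 0.058 to 0.987. Apoptosis genes and microRNA biogenesis genes had medians of 0.03 with a test pointing down, while interneuron markers and tricarboxylic acid cycle genes had medians of -0.01 and means of 0.01.

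The Gfap call in MPTP ended with arrays centred on their medians (adjusted p = 0.081), with no filter (0.143), with only MPTP and control in the fit (0.112) and with array weights (0.055), at log2 fold changes of 1.06 to 1.14. It also ended without each array in turn except control 3, at 1.06 to 1.19 and adjusted p-values of 0.052 to 0.322.

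Between METH and MPTP no gene passed the test. Gfap had a log2 difference of -0.01 ± 0.13 (METH minus MPTP), with signals of 12286 ± 1444 and 12324 ± 1152 (SD, n = 3 each). Immediate early genes were higher in METH than in MPTP for 20 of 24, with a median of 0.22, and complexes II to V were lower in METH for 34 of 39, with a median of -0.08. Both of these calls were lost when the correlation between genes was estimated (adjusted p = 0.605 with an estimated correlation for each). Microglia and interferon-responsive genes did not pass, with medians of 0.04 (adjusted p = 0.303) and 0.06 (adjusted p = 0.131).

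The smallest adjusted p of a gene in METH against MPTP was 0.999 in limma. At an unadjusted p under 0.05 there were 227 genes, 124 higher and 103 lower in METH, where chance gives 398, and the groups did not overlap for 7.1% of genes, where chance gives 10%. The smallest p-values belonged to Syf2, a splicing factor, at 0.56 ± 0.10, Lor at 1.03 ± 0.20, Brd8 at 0.79 ± 0.17, Tfdp1 at -0.53 ± 0.12 and Gstt1, a glutathione transferase, at -0.63 ± 0.15. The others among the 10 smallest were Prr3, Klf2, Fam110c and Carns1 at 0.41 to 0.47 and Ss18l2 at -0.37 ± 0.09. Th had 0.17 ± 0.16 and Ppp1r1b 0.12 ± 0.11.

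The immediate early gene difference between METH and MPTP had adjusted p = 6.28e-05 (adjusted p = 0.605 with an estimated correlation), and the call ended without MPTP 2 (median 0.15, adjusted p = 0.084). Dusp6, Dusp14 and Fos had 0.41 ± 0.15, 0.39 ± 0.16 and 0.28 ± 0.13, and Ier2 had -0.59 ± 0.19. Complexes II to V had adjusted p = 5.50e-04 (adjusted p = 0.605 with an estimated correlation), with Sdhd, Atp5g2 and Cox8a at -0.36 ± 0.17, -0.18 ± 0.10 and -0.16 ± 0.09, and the list's median was -0.05 with quantile normalization and with cyclic loess. Oligodendrocyte and myelin genes were lower in METH for 21 of 24, with a median of -0.09 (adjusted p = 0.007, and adjusted p = 0.652 with an estimated correlation). Olig2 had -0.28 ± 0.10 and Aspa -0.20 ± 0.09, whereas Sox10 had 0.30 ± 0.10. The myelin call ended without METH 2 (median -0.05, adjusted p = 0.324) or MPTP 1 (0.077). Proteasome subunits were lower in METH for 28 of 32, with a median of -0.05 (adjusted p = 0.009, and adjusted p = 0.646 with an estimated correlation) and Psma5 at -0.35 ± 0.12. That call ended with the mean of all probe sets (0.103) and without METH 1, METH 2 or MPTP 1 (0.06 to 0.324), and the median was -0.09 without MPTP 2 and -0.08 with arrays centred on their medians.

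Chaperone and unfolded protein response genes were higher in METH than in MPTP for 25 of 37, with a median of 0.04 (adjusted p = 0.018, and adjusted p = 0.652 with an estimated correlation). The heat shock genes Dnajb1, Hspa1a and Hspa1b had 0.43 ± 0.13, 0.65 ± 0.28 and 1.10 ± 0.50. The chaperone call ended with no filter (adjusted p = 0.193), a filter at the 60th percentile (0.129) and without METH 1, METH 3, MPTP 2 or MPTP 3 (0.078 to 0.216), with medians of 0.01 without MPTP 3 to 0.10 without METH 2. Arrays centred on their medians gave a chaperone median of 0.01, cyclic loess 0.07 and the mean of all probe sets 0.10. Choroid plexus markers had a median of 0.31 (adjusted p = 0.049, and adjusted p = 0.728 with an estimated correlation), with Ttr at 1.60 ± 0.96, and the call ended with array weights (0.15), the mean of all probe sets (0.267), _x_at and _s_at probe sets left out (0.162), cyclic loess (0.0505), and without control 2, control 3, METH 1, METH 2, MPTP 2 or MPTP 3 (0.055 to 0.863). Without METH 2 the median was 0.15. In every list of METH against MPTP 0 genes passed when adjusted over the list alone, and 0 over all genes tested. With fry all 6 calls ended (adjusted p of at least 0.394). The remaining 25 lists did not pass (adjusted p = 0.063 to 0.996), among them glucocorticoid-responsive genes, with a median of -0.01 and a test pointing up.

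**Figure D3:**
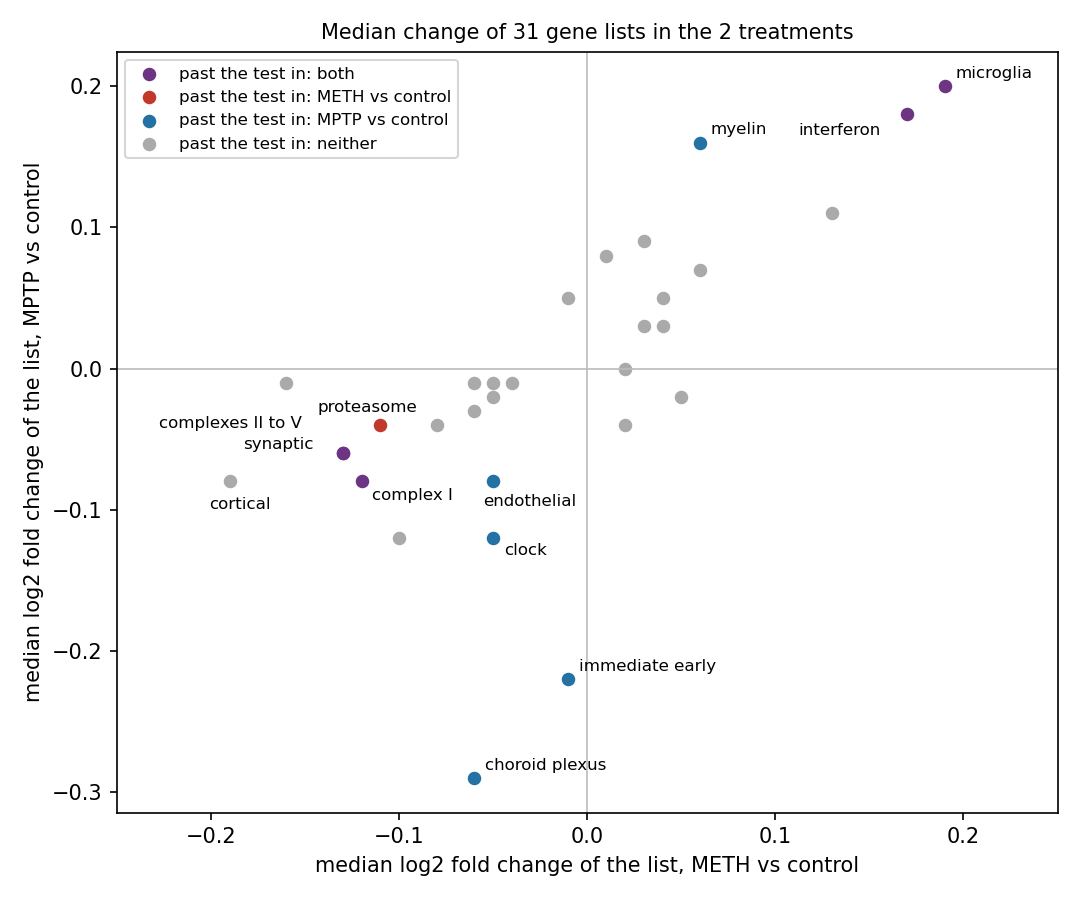
Median log2 fold change of each of 31 gene lists in METH against control (horizontal axis) and in MPTP against control (vertical axis), with colours for the comparisons in which a list passed the set test at the preset correlation. Microglia and interferon lists lie highest in both, at 0.17 to 0.20; both axes use the same 3 control arrays.

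Gfap passed the test after both toxins, and 5 lists did: microglia, interferon-responsive, complex I, complexes II to V and presynaptic genes. The comparisons share their controls, and how many lists unchanged groups would share was not simulated. All 5 list calls were lost with an estimated correlation in both comparisons (adjusted p = 0.099 to 0.562 in METH and 0.231 to 0.525 in MPTP). Across the 7964 genes, which are not independent replicates, the METH and MPTP log2 fold changes had a Pearson r of 0.672. Unchanged groups simulated against the same kind of shared control gave 0.501 (0.45 to 0.531 in 100 simulations). These simulations drew each gene independently, so their ranges leave out correlation between genes and may be too narrow. The covariance was 0.0218 against a simulated 0.0135, a difference of 0.0083. At an unadjusted p under 0.05 in both comparisons, 203 genes had the same sign and 1 had opposite signs, where simulations gave 79 to 125 of the same sign. Of the 203, 153 were higher and 50 lower. Independent lists would give 14.7 and 4.73, values that leave out the shared controls and so lie far under what the simulations give with no effect. The 3 controls cannot be split into parts of at least 2. Part of this excess may therefore come from the shared controls, through shifts common to many genes that the simulations leave out. Over all 3 groups Gfap was 1 gene past limma's F-test (adjusted p = 0.042), with 460 genes at an unadjusted p under 0.05.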

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

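Log2 of the value plus 100, cyclic loess, counts at an unadjusted p, matched random lists and the exact tests of list scores were chosen after the results were seen; the other alternatives were planned. Dim probe sets limit the depth, since their spread within groups is largest. Across 505 single results (named genes and lists) there were 10507 values under alternatives. Of these, 10086 kept their sign (for lists, the direction of the test) and their side of the threshold. Few single results were calls: Gfap in both comparisons with control, and 6, 10 and 6 lists in METH, MPTP and METH against MPTP. Most of the 10086 are therefore uncalled results that stayed uncalled, and they do not show that the calls are stable. With the sign kept, 136 lost a call and 67 gained one. A further 218 changed sign without a call in either setting, and 0 changed sign with a call. In METH against control, MPTP against control and the 3-group test, arrays centred on their medians gave 0, 0 and 0 genes and all probe sets gave 2, 2 and 2, the latter because both Gfap probe sets count. Genes passing in both comparisons were 0 and 2 under these settings. With no filter MPTP gave 2 genes, Oas1b and Pramel25, METH gave 10 lists, and the correlation of log2 fold changes was 0.586; the mean of all probe sets gave 10 METH lists. With only the compared groups in the fit MPTP gave 0 genes and both comparisons shared 0, METH's 1 gene being Pom121; array weights gave 0 and 0 likewise. Camera with an estimated correlation gave 0, 0 and 0 lists in METH, MPTP and METH against MPTP. Fry gave 0 lists in MPTP and 0 in METH against MPTP, and 4 in METH (microglia, interferon-responsive, complexes II to V and reactive astrocyte genes). For the settings other than all probe sets, the cause was not tested.

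The replicate numbers do not pair the arrays: same-numbered arrays of different groups had residual correlations of -0.15 to 0.05 in 9 pairs, and 0 of 9 arrays correlated best with their own number. With the replicate number as a block, 0 genes passed in METH, 0 in MPTP, 0 in the 3-group test and 0 in both comparisons.

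Leaving out 1 array gave 0 to 2 genes in METH, 0 to 2 in MPTP, 0 to 0 in METH against MPTP, 0 to 2 in the 3-group test and 0 to 1 in both comparisons. The correlation was 0.588 to 0.745. Lists numbered 5 to 8 in METH, 4 (without control 1) to 11 in MPTP, where 6 passed without MPTP 3, and 3 (without METH 2 or MPTP 2) to 9 in METH against MPTP. Without METH 2 the genes past the test in METH were Gfap and Lor, without MPTP 2 Gfap and Pom121, and without control 3 those in MPTP were Gfap and Timp2. Leaving out an array lowers the residual degrees of freedom.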

Other observations

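Tests chosen after the result was seen were those over the 84 splits, the ranks among matched lists, cyclic loess, and the tests on the share of neurons, blood, METH 2, cortical tissue and the array behind the METH against MPTP difference.

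Lists that did not pass against control held some large single values. Hspa1b, an inducible heat shock gene, had a METH against control log2 fold change of 1.75 ± 0.50, with all 3 METH arrays above all 3 control arrays and an adjusted p of 0.494. Among antioxidant genes the lipid peroxidase gene Gpx4 and the superoxide dismutase gene Sod1 had -0.32 ± 0.10 and -0.22 ± 0.08 after METH, and the list of 29 had a median of -0.06 (adjusted p = 0.207). Metallothionein Mt2 had 0.24 ± 0.09 after MPTP, where the list had a median of -0.01 (adjusted p = 0.735). Striatal interneuron markers had medians of -0.16 (adjusted p = 0.11) after METH and -0.01 (adjusted p = 0.716) after MPTP. Cytosolic ribosomal proteins and microRNA biogenesis genes, which bear on translation and silencing, had medians of -0.04 and 0.04 after METH (adjusted p = 0.233 and 0.98) and -0.01 and 0.03 after MPTP (adjusted p = 0.488 and 0.987).

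Below the filter, the interferon-induced gene Oas1b had signals of 676 ± 58.7 in METH, 619.9 ± 42.7 in MPTP and 249 ± 18.3 in control (SD, n = 3 each). Pramel25 had 5.4 ± 2.0, 4.1 ± 1.0 and 41.1 ± 2.1, near the bottom of the intensity range. With no filter Oas1b had adjusted p = 0.015 in METH and 0.03 in MPTP, and Pramel25 0.066 and 0.037. Pom121, a nuclear pore gene, had 10044 to 15118 on all METH arrays and on MPTP 1 and MPTP 3, and 3413 to 4482 on the controls and MPTP 2. These genes were named after their values were seen.

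Microglia and macrophage markers were higher after both toxins, and 1 of 84 splits of the arrays into 6 and 3, the real one, gave a score difference as large (0.22, highest other 0.187). This exact permutation p of 0.012 is the smallest the splits allow and is 0.123 adjusted over 31 lists. Interferon-responsive genes (0.232) and reactive astrocyte genes (0.115) reached the same exact p, so the test does not single out microglia. A drift with intensity alone is argued against only as far as genes move independently. The list median stood at percentile 100 of lists matched on expression in both comparisons, but these random lists leave out correlation between genes. Lists that did not pass also reached the tails, such as spiny neuron markers at percentile 99.61 in METH and astrocyte markers at 99.88 in MPTP. A lower share of neurons was not settled. Microglia minus endothelial scores differed by 0.286 (exact permutation p = 0.012, the smallest possible), which goes against an equal rise of both. But the microglia score alone gave the same p, and the endothelial score was lower in treated arrays (-0.066). Other glial scores were higher: myelin 0.119, oligodendrocyte precursor 0.062 and astrocyte 0.041 (exact permutation p = 0.095 to 0.25). Blood in the tissue cannot be told apart: after regression on the blood score of 4 genes the difference was 0.122 (exact permutation p = 0.024), 55.2% of its size, but 37.8% to 74.2% when 1 array was left out. A microglial or macrophage response to both toxins, with Gfap as the astrocyte counterpart, may be a hypothesis to follow and was not tested further.

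Respiratory chain genes were lower in METH and in MPTP by list median. With both toxins pooled, 3 of 84 splits gave a score difference as large as the real -0.092 (highest other 0.093). This puts chance under 0.05 for the pooled score alone but not over 31 lists (complexes II to V, adjusted p = 0.185). Scores were -0.094 to -0.045 in METH, -0.043 to 0.031 in MPTP and 0.03 to 0.086 in control. MPTP 1 (0.031) lay above control 2 (0.03), so the pooled splits do not speak for MPTP alone. A drift with intensity alone was not settled in METH. Both medians lay at or under percentile 0.27 of matched lists, but random lists leave out correlation between genes. Lists that did not pass also reached the tails in METH, with spiny neuron markers at percentile 99.61 and chaperone genes at 99.54. Cyclic loess reduced both respiratory medians to -0.07. In MPTP a drift cannot be told apart, complexes II to V lying at percentile 3.74 (-0.02 with cyclic loess) and complex I at 0.6. METH 2 as the cause is argued against, since both METH calls remained without it at the preset correlation (higher adjusted p = 0.0047), though with all arrays they were lost at an estimated one (adjusted p = 0.283 and 0.122). A lower share of neurons as the whole cause cannot be told apart. Microglia and endothelial scores moved apart (exact permutation p = 0.012), but these scores hold no neuronal or respiratory chain genes and cannot decide. Spiny neuron markers did not decide either: respiratory minus spiny neuron scores differed by -0.079 (exact permutation p = 0.274). Which cells carry the difference, and whether a loss of one neuron type adds to it, was not tested.

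Immediate early genes were lower in MPTP than in METH and control at the preset correlation, and both calls were lost with an estimated one (adjusted p = 0.605 and 0.397). More cortex in the METH dissections was not settled. The cortical median difference was -0.087 with a 95% bootstrap upper bound of 0.052, where 0.223 is needed if both lists change equally with cortex. The bound is on a median over genes and leaves out the spread between mice. Cortical scores of single arrays overlapped, at -0.212 to 0.07 in METH and -0.116 to 0.093 in MPTP. More cortex in the control dissections cannot be told apart: the cortical median was -0.082 with a lower bound of -0.295, and -0.225 is needed. For METH against MPTP, the call rests on MPTP 2, since it ended without that array (highest adjusted p over the 9 arrays 0.0842). The median without MPTP 2 was 0.15, against 0.22 with all arrays, so this array may carry part of the difference. The MPTP against control call remained at the preset correlation without each array (highest adjusted p 0.0299), with a smaller median of -0.13 without MPTP 2. Handling or time of day at dissection was not tested.

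For groups of 3 against 3 the 10 splits are too few for a share under 0.05. The real METH split gave 1 gene and 6 lists, and the highest of the other splits 0 and 5 (1 of 10 and 1 of 10 as large). The real MPTP split gave 1 gene and 10 lists, the highest other 0 and 9 (1 of 10 and 1 of 10). METH against MPTP gave 0 genes and 6 lists, the highest other 0 and 6 (10 of 10 and 2 of 10). At the preset correlation, lists thus also passed on arrays with mixed labels. In the 3-group test 8 of 100 splits gave at least the real count of 1 gene, with a highest other count of 1, so chance was not excluded.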
